A study of Homo sapiens with 6 samples.

How the data were processed

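RNA of VCaP and LNCaP cells carrying a hairpin against PCAT29 was compared with RNA of the same line carrying a non-targeting hairpin on 6 two-colour Agilent arrays. Per the labels, the knockdown RNA carried Cy5 and the control RNA Cy3 on every array, so no array had the dyes exchanged, and knockdown had been checked by quantitative PCR, whose values were not used here. Each scanner file holds 1 array of 45015 spots, 43376 of them not controls. Per the file headers, the intensity columns hold the mean signal and the median local background of each spot in each channel as scanned. Per the file headers, the processed intensity columns were background-subtracted and dye-normalized by Feature Extraction 9.5.1.1, while the submitters' processing notes name version 8.5.1.1. The log10 ratio of Cy5 over Cy3 processed signals was computed by the same software, per the file headers. The other columns used are flags for control spots, outliers, saturation and signal above background, per the file headers.

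The authors also deposited a table of log2 ratios. Its columns had medians of -0.05, -0.05, -0.05, -0.06, -0.07 and 0.01 (log2) and, against the log10 ratio of the same array turned to log2, slopes from 0.996 to 1 and correlations of 0.782, 0.946, 0.930, 0.974, 0.970 and 0.998. Its log base and direction follow from this, and the further normalization the authors applied to it stays unknown. It served as an alternative.

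From the mean signals and local backgrounds, each channel was corrected with the normexp method (offset 50), and log ratios were normalized within each array by loess, with control spots at weight 0. Spots flagged as outliers and between 0 and 81 spots per array whose local background lay more than 10 median absolute deviations above the array's median were left out before normexp was fitted. This departs from a fit on all spots. It was chosen after seeing the data, because on the replicate 2 arrays of VCaP the fit on all spots put the control channel's background at -901 and -678, against 11.7 and 9.04 without those spots. The fit on all spots was kept as an alternative. Control spots were then dropped and spots of the same probe averaged, giving 41000 probes.

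Probes were named by the gene of their accession in a reference table of symbols, which gave 16038 of 30719 genes, and by the file's own name otherwise. Of several probes of a gene, the brightest over all arrays stood for the gene. Where an alternative changed the processing of the spots, the brightest probe was chosen anew. A gene was tested when its probe was well above background in at least 1 channel on at least 2 arrays, which left 22662 genes, 13162 of them named through an accession and 6807 with several probes. A gene whose channel was saturated, or not well above background, on every array of a line has only a bound there. The bound sets the mean of the brighter channel against the mean of the dimmer one, raised on each array to at least the lowest signal among probes well above background, per channel after loess and Aquantile normalization, and it is open to dye bias.

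Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each cell line over all 6 arrays, and each mean was tested against 0. The difference between the line means was tested in the same fit. Hairpins were compared in a fit of 4 group means, in which the VCaP replicate arrays alone carry the spread. With 1 array per hairpin, no test of the LNCaP hairpins is given. P values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. If the arrays of a line shared 1 control RNA, a test of the ratio against 0 leaves out the control's own spread. Such a test also cannot separate a change from a gene-specific dye bias, which cancels only in the differences between lines and between hairpins. The labels do not say that the replicate arrays came from separate cultures, so the p values measure the spread between these arrays, which may be technical.

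Lists of 31 pathways, gene families and cell type markers were fixed before the data were examined, as were the tests, the alternatives apart from the normexp fit on all spots, and the rule for named genes. Some genes picked by that rule are counted but not reported here. The lists were tested with camera (preset correlation 0.01) and, as alternatives, with camera using an estimated correlation and with fry, and adjusted over the 31 lists. With an estimated correlation no list passed in any comparison, also where that correlation lay below the preset one. Such a loss alone is therefore not a measure of correlation within a list. Comparisons of hairpins were added for the lists after the data had been seen. Named genes were the 12 highest and 12 lowest means of each line among genes with a symbol that passed with the same sign on every array of the line and a probe well above background, the 8 highest and 8 lowest of those changed the same way in both lines, the 6 highest and 6 lowest differences between lines and between VCaP hairpins, filled up to 5 with genes that did not pass, and up to 4 members of each list described. The correlation from a shared control was simulated with unchanged groups and a control assumed to deviate as much as a single VCaP array.

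Alternatives were no background correction, the scanner's own log ratio, median centring without loess, scaling to equal spread, other filters on dim probes, genes with saturated spots left out, the mean over a gene's probes, the authors' table, 4 group means, averaged replicate arrays, each line on its own arrays, robust eBayes with an intensity trend, a 1.5-fold minimum, a block on the VCaP replicate number, and leaving out each array. The fit was tested on simulated data with 50 changed genes per fold size. At 1.25-fold it found 100% of them in VCaP and in LNCaP, and 82% for the difference between lines and for the difference between VCaP hairpins; at 1.5-fold and above it found 100% for each of these comparisons. It called 4, 13, 5 and 19 unchanged genes of 22662. Camera found the 1 shifted list among 31 and called 0 others. The simulated genes were independent and had only the spread between VCaP replicate arrays of a hairpin. Differences between hairpins, the wider log ratios of the LNCaP arrays and correlation within lists were left out. These figures therefore describe a simpler case than the data. No sample was left out.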

Results

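Gene expression was measured on 6 Agilent arrays of 2 established prostate cancer cell lines, VCaP and LNCaP, after knockdown of the long noncoding RNA PCAT29. Each array set cells carrying a hairpin against PCAT29, labelled with Cy5, against cells of the same line carrying a non-targeting hairpin, labelled with Cy3, so that a log2 ratio above 0 means more RNA after knockdown. VCaP with hairpin 1 was measured on 2 arrays and VCaP with hairpin 2 on 2 arrays, and LNCaP with each hairpin on 1 array. The median spot intensity before background correction ranged from 223 to 274 in the knockdown channel and from 141 to 197 in the control channel. Between 66.3% and 72.4% of the spots stood well above background in the knockdown channel, and between 65.1% and 67.8% in the control channel. Of 30719 genes on the array, 22662 were bright enough to be tested, and the small number of arrays limits the precision of each value.

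No probe of the array carried the name PCAT29, and probes were matched to it by name only, so the knockdown itself was not read from these data. The neighbours of PCAT29 on chromosome 15 were measured as a list of 9 genes. In VCaP, RPLP1, a ribosomal stalk protein, rose by 0.42 ± 0.11 and KIF23, a kinesin of cell division, fell by 0.24 (log2, SD, n = 4), and 7 genes of the list did not pass. In LNCaP, KIF23 fell by 0.21 and THSD4, an extracellular matrix protein, fell by 0.30 (log2), and 7 did not pass. The list as a whole showed no shift in VCaP (camera adjusted p = 0.817) or in LNCaP (camera adjusted p = 0.381).

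The first comparison asked what changed in VCaP cells when PCAT29 was lowered. GIPR, the receptor of a gut hormone that raises insulin release, rose by 1.06 ± 0.07 on the log2 scale (SD, n = 4), which was 2.08-fold and the highest mean among the named genes without saturation. Ribosomal protein genes made up 7 of the 12 named genes with the highest means, and RPL13A rose by 0.72 ± 0.08, RPS10 by 0.66 ± 0.08 and RPS14 by 0.65 ± 0.06 (log2, SD, n = 4). The ubiquitin-conjugating enzyme UBE2E1 rose by 0.71 ± 0.21 and the protease inhibitor A2ML1 by 0.64 ± 0.06 (log2, SD, n = 4). SPON2, a secreted matrix protein, was saturated in the knockdown channel on all 4 arrays and was at least 1.74-fold higher. RPS27 was likewise saturated and, by its brightest probe, at least 1.57-fold higher. The actin-like gene ACTL8 fell by 1.05 ± 0.42 (log2, SD, n = 4), the only named gene in VCaP that was more than 2-fold lower.

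Other genes that fell in VCaP did so by less. They included C1QTNF5, a secreted relative of complement C1q, at -0.50 ± 0.22, the serine-degrading enzyme SDS at -0.49 ± 0.06, the ribosome maturation factor TSR2 at -0.48 ± 0.06 and the histone chaperone HIRA at -0.45 ± 0.11 (log2, SD, n = 4). The actin-severing protein CFL1 stood at -0.44 ± 0.11, the phosphatase PPP5C at -0.44 ± 0.06 and the heparan sulphate proteoglycan SDC4 at -0.41 ± 0.06. CHRAC1, a histone-fold protein of chromatin remodelling, SNRPB, a core spliceosome protein, the kinase CAMK1 and NBL1, an antagonist of bone morphogenetic proteins, stood at -0.40, -0.40, -0.39 and -0.39 (log2). By the rule that picked them, all 12 genes that rose and all 12 that fell had the same sign on the 4 VCaP arrays. Their limma adjusted p lay between 1.91e-05 for GIPR and 0.0258 for SDC4. Probes of one gene did not always give the same value. A further, dimmer probe of GIPR averaged 0.06 (in LNCaP 0.20), one of SDS 0.01 and one of SDC4 0.04 (log2). The other probes of RPS14 averaged 0.07, 0.49 and 0.09, those of RPL13A 0.40 and 0.22, and those of RPS10 between 0.18 and 0.52. That of RPS27 averaged 0.44 (log2), lower than the bound from its saturated probe. With all spots kept in the background fit GIPR stood at 0.05 in VCaP and did not pass. The brightest probe was chosen anew there, so this value, close to the 0.06 of the dimmer probe, may belong to that probe. The call of SDC4 was lost without any single VCaP array, with adjusted p of 0.101 (VCaP-sh1 replicate 1), 0.0904 (VCaP-sh1 replicate 2), 0.106 (VCaP-sh2 replicate 1) and 0.0849 (VCaP-sh2 replicate 2).

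Across all genes, 3896 changed in VCaP (limma, Benjamini-Hochberg adjusted p below 0.05), of which 2240 rose and 1656 fell. The changes were small, with a median of 1.13-fold, and 22 of the genes changed at least 1.5-fold. Without any single VCaP array the count was 1179 (VCaP-sh1 replicate 1), 1218 (VCaP-sh1 replicate 2), 1200 (VCaP-sh2 replicate 1) or 1360 (VCaP-sh2 replicate 2), and without either the LNCaP-sh1 or the LNCaP-sh2 array it was 6987. With the replicate arrays of each hairpin averaged first, so that the hairpins were the replicates, 1 gene passed. Median centring in place of loess moved the median of all genes to 0.14 in VCaP and 0.18 in LNCaP (log2), and 73.6% of the calls in VCaP were then higher in place of 57.5%.

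Of the 31 gene lists fixed beforehand, only the ribosomal proteins shifted in VCaP. Of their 32 genes, 25 rose, 0 fell and 7 did not pass, and 26 rose when adjusted over the list alone. Their mean was 0.32 (log2), with camera adjusted p = 5.9e-19, and adjusted p = 0.517 with an estimated correlation. The mean was 0.09 in the scanner's own log ratio and in the authors' table (adjusted p = 0.0278 and 0.0224) and 1.02 with median centring. The smallest adjusted p belonged to RPS10, RPS20, RPL35 and RPS14, and RPL35 rose by 0.57 ± 0.03 (log2, SD, n = 4) but stood at 0.05 in the scanner's own log ratio. Genes outside the list and nearest to it in brightness were higher too. They averaged 16.8 in log2 brightness, against 17.3 for the ribosomal genes. Only the list itself and names of the form RPL, RPS, MRPL or MRPS with a number were kept out of the matching. Ribosomal probes under other names may therefore be among the matched genes. In 95% of 1000 random sets, each with 1 gene of matching brightness per ribosomal gene, the median log2 ratio in VCaP lay between 0.25 and 0.40, around the 0.33 of the ribosomal genes. The sets drew repeatedly on the same 112 genes, so they were not independent. The brightest 2267 genes tested, dimmer on average than the ribosomal genes, had a median of 0.0039 in VCaP (log2).

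The remaining 30 lists had camera adjusted p between 0.0988 and 0.992 in VCaP. The unfolded protein response came nearest, with 0 genes up and 6 down of 23. Among the androgen-induced genes, 3 rose and 3 fell of 35, and among the androgen-repressed genes 0 rose and 3 fell of 11. The p53 targets held 2 that rose of 26, the epithelial adhesion genes and keratins 1 that rose and 6 that fell of 24, the apoptosis regulators 6 that fell of 23, and the mesenchymal and migration genes 0 that passed of 20.

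The second comparison asked the same of LNCaP. GIPR rose 2.39-fold (n = 2, with an SD of 0.12 on the log2 scale), and was again the highest mean among named genes measured in both channels. OAZ1, which restrains polyamine synthesis, rose by 0.85 ± 0.02, the thyroid hormone carrier TTR by 0.74 ± 0.52, the ribosomal protein paralog RPL22L1 by 0.73 ± 0.22, the zinc finger gene TSHZ3 by 0.72 ± 0.64 and the lactate dehydrogenase subunit LDHB by 0.66 ± 0.23 (log2, SD, n = 2). The ribosomal protein genes RPL38, RPL14, RPL41, RPS27 and RPS20 rose by 0.72, 0.68, 0.68, 0.67 and 0.64 (log2), with RPS27 saturated in the knockdown channel on 1 of the 2 arrays, while the other probes of RPL14 stood at 0.27 and 0.08. OR2W3, an olfactory receptor gene, was not well above background in the control channel on both arrays and was at least 1.48-fold higher.

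The named genes that fell in LNCaP did so by much more than those in VCaP. The sizes are not like for like, since LNCaP means rest on 2 arrays with wider log ratios. The SD across genes was 0.24 and 0.20 on the LNCaP arrays, against 0.13 to 0.14 on the VCaP arrays. TMCC2, a transmembrane protein with coiled coils, fell to -3.39 ± 0.39, the secreted protein gene LGI4 to -2.69 ± 0.31 and LY6G5C, of the lymphocyte antigen 6 family, to -2.48 ± 0.30 (log2, SD, n = 2). The zinc finger gene ST18 fell to -1.76 ± 0.05, the tudor domain gene TDRD10 to -1.72 ± 0.43, POMK, a kinase that builds the sugar chain of dystroglycan, to -1.53 ± 0.16, the G protein subunit GNG13 to -1.28 ± 0.47 and the calcium channel gene ORAI3 to -1.18 ± 0.16. CACHD1 fell to -1.05 ± 0.16 and the dopamine receptor gene DRD5 to -1.05 ± 0.21 (log2, SD, n = 2). The knockdown channel of ST18, CACHD1 and DRD5 was well above background on 1 of the 2 arrays. SDCBP2 fell to a mean of -1.18, with -2.01 for hairpin 1 and -0.35 for hairpin 2. RGMA, a guidance cue and bone morphogenetic protein co-receptor, was 3.99-fold lower by its brightest probe and stood at 0.16 by its other probe, and its value was 0.094 without background correction and 0.25 in the scanner's own log ratio, where the other probe is the brighter. Further probes of TMCC2 at 0.10 and of TDRD10 at 0.04 were not well above background in the LNCaP controls. The calls of TTR and TSHZ3 were lost without the LNCaP-sh1 array, at values of 0.38 and 0.27 (adjusted p = 0.0623 and 0.0835), and those of RPL22L1, RPL41, RPS27 and LDHB in the scanner's own log ratio, at values of 0.32, 0.29, 0.23 and 0.32 (adjusted p = 0.0730, 0.0565, 0.210 and 0.0553), where TSHZ3 did not pass either (adjusted p = 0.0548).

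In LNCaP, 4026 genes changed (limma, adjusted p below 0.05), of which 1957 rose and 2069 fell, with a median of 1.20-fold. At least 1.5-fold changes were found for 153 genes, 32 higher and 121 lower, and 38 genes were at least 2-fold lower against 1 that was at least 2-fold higher. Because LNCaP had 1 array per hairpin, this test borrowed most of its estimate of spread from VCaP, and with LNCaP fitted on its own 2 arrays 173 genes passed. Without the VCaP-sh2 replicate 1 array the count was 2618, without the LNCaP-sh2 array 6255, and with median centring 74.8% of the calls were higher in place of 48.6%.

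Of the 31 lists, 6 shifted in LNCaP. Ribosomal proteins were higher, with 22 of 32 genes up, 0 down and 10 not passing, 25 up and 1 down when adjusted over the list alone, and a mean of 0.31 (log2, camera adjusted p = 7.17e-13, and adjusted p = 0.619 with an estimated correlation). RPS2 rose by 0.62 and RPL13 by 0.50 (log2). Genes of matching brightness had medians between 0.23 and 0.38 in 95% of 1000 random sets, around the 0.27 of the list (log2). These sets again drew repeatedly on the same 112 genes. In the scanner's own log ratio the list's mean was 0.07 and its call was lost, with adjusted p = 0.282.

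The other 5 lists were lower in LNCaP. Of the 26 p53 targets, 1 rose, 6 fell and 19 did not pass (9 fell when adjusted over the list alone), with a mean of -0.19 (log2, camera adjusted p = 0.0158, and adjusted p = 0.619 with an estimated correlation). PHLDA3, an inhibitor of AKT signalling, fell to -0.47 ± 0.21, the antiproliferative gene BTG2 to -0.37 ± 0.18, and the DNA repair genes XPC and DDB2 to -0.25 ± 0.08 and -0.55 ± 0.42 (log2, SD, n = 2). Of the 35 androgen-induced genes, 2 rose, 8 fell and 25 did not pass (3 rose and 11 fell when adjusted over the list alone), with a mean of -0.12 (camera adjusted p = 0.0382, and adjusted p = 0.619 with an estimated correlation). The protease gene TMPRSS2 fell to -0.45 ± 0.22, KLK2, a kallikrein, to -0.47 ± 0.35 and the acyl-CoA synthetase ACSL3 to -0.33 ± 0.14. KLK3, which encodes prostate-specific antigen, rose by 0.35 ± 0.01 by its brightest probe and averaged -0.19 over its probes.

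Of the 24 epithelial adhesion genes and keratins, 1 rose, 8 fell and 15 did not pass (1 and 10 when adjusted over the list alone), among them the claudins CLDN4 at -0.46 and CLDN7 at -0.51, E-cadherin (CDH1) at -0.35 and the transcription factor GRHL2 at -0.31 (log2). Of the 20 mesenchymal and migration genes, 1 rose, 4 fell and 15 did not pass (1 and 4 when adjusted over the list alone). The matrix protein tenascin C (TNC) fell to -0.53 ± 0.03, vimentin (VIM) to -0.30 ± 0.12 and the matrix protease MMP9 to -0.27 ± 0.01, while SNAI1, a repressor of E-cadherin, rose by 0.22 ± 0.10 (log2, SD, n = 2). Of the 32 genes of G2/M and mitosis, 0 rose, 3 fell and 29 did not pass (0 and 3 when adjusted over the list alone), with CDK1 at -0.26, CENPF at -0.21 and KIF23 at -0.21. The camera adjusted p was 0.0382 for each of these 3 lists, and adjusted p = 0.619 with an estimated correlation.

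The calls of the 5 lower lists were lost without the LNCaP-sh1 array. The means were then -0.04 for p53 targets (adjusted p = 0.589), -0.02 for androgen-induced genes (0.772), -0.04 for G2/M and mitosis (0.589), -0.08 for epithelial adhesion genes and keratins (0.366) and -0.09 for mesenchymal and migration genes (0.579), against -0.19, -0.12, -0.07, -0.12 and -0.14 with it (log2). The calls were also lost in the scanner's own log ratio for androgen-induced genes (adjusted p = 0.120), G2/M and mitosis (0.132) and mesenchymal and migration genes (0.0648), though their means there were -0.12, -0.04 and -0.21 (log2) against -0.12, -0.07 and -0.14, in the authors' table for these (0.106, 0.143 and 0.0627) and the epithelial list (0.0549), and with fry for p53 targets (0.131), androgen-induced genes (0.134) and G2/M and mitosis (0.109). Further calls were lost for G2/M and mitosis with scaling to equal spread (0.0523), each line on its own arrays (0.0591) and all spots in the background fit (0.0660), for the epithelial list with all spots (0.0637) and with 4 group means (0.0581), and for the mesenchymal list without a filter on dim probes (0.115). Single calls lost without the LNCaP-sh1 array were KLK2, XPC, CDK1, CENPF, KIF23, VIM and SNAI1, with adjusted p between 0.0501 and 0.120. With median centring the mean of the G2/M list was 0.38, that of the epithelial list 0.25, that of the androgen-induced list 0.16 and that of the p53 targets 0.14 (log2), and CDK1, CENPF, KIF23, CDH1, GRHL2, TMPRSS2 and ACSL3 also stood above 0. The remaining 25 lists had camera adjusted p between 0.054 for the heat shock response, with 4 genes up of 16, and 0.984.

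**Figure D1:**
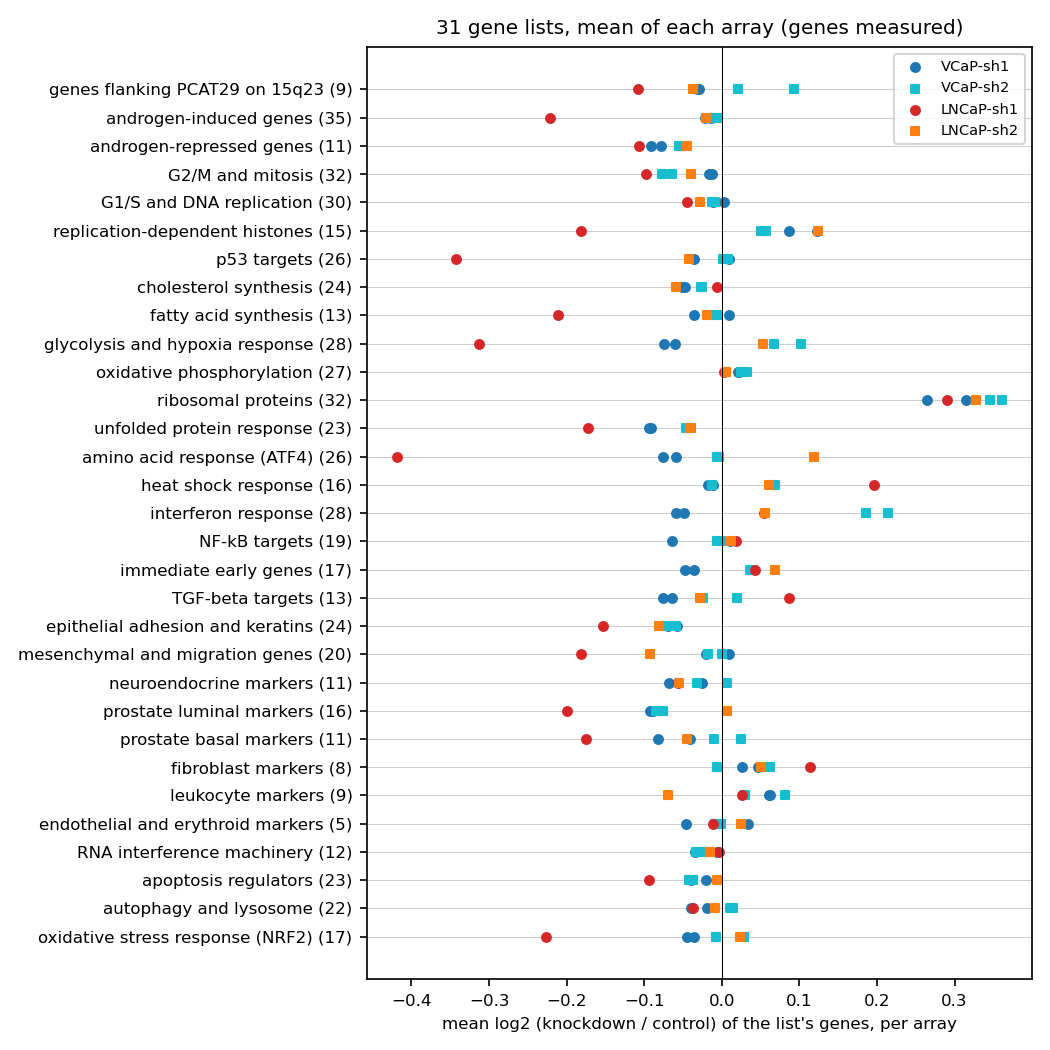
Mean log2 ratio of knockdown over control for each of the 31 gene lists, 1 point per array, with the number of genes measured in parentheses. Circles are hairpin 1 and squares hairpin 2, blue for VCaP and red or orange for LNCaP. The ribosomal proteins lie above 0 on all 6 arrays, and the LNCaP-sh1 array holds the lowest mean for the p53 targets.

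Genes changed in both lines were compared next. Of 22662 genes, 866 rose in both lines where independent lists of these sizes would share 193, and 611 fell in both where they would share 151. The lines share each gene's estimate of spread, so a gene with little spread passes more easily in both. Independent lists therefore understate the overlap without a shared change. GIPR, RPL13A, RPS14, OAZ1, RPS20 and RPL41 (saturated on 1 VCaP array) were among the highest means over the lines, as was RPS27, whose saturation leaves only a bound in VCaP, and CFL1, TSR2, STBD1, SDC4, SDS, NSFL1C, CARTPT and PSMD11 the lowest. STBD1, which tethers glycogen to membranes, stood at -0.34 ± 0.06 in VCaP and -0.56 ± 0.32 in LNCaP, and PSMD11, a proteasome subunit, at -0.36 ± 0.01 and -0.45 ± 0.01 (log2, SD, n = 4 and n = 2). NSFL1C, a cofactor of the p97 ATPase, stood at -0.23 and -0.59, and CARTPT, a neuropeptide precursor, at -0.27 and -0.54. Another 41 genes changed in opposite ways, and for 36 of these the difference between the lines passed. Without the LNCaP-sh1 array SDC4 stood at -0.09 in LNCaP and did not pass. With median centring NSFL1C and PSMD11 stood at 0.013 and 0.0050 in VCaP. In LNCaP the other probes of RPS14 stood at -0.02, 0.35 and -0.09, and those of RPL13A at 0.27 and 0.13. The other probes of SDS and SDC4 stood at -0.03 each there (log2). Those of NSFL1C stood at -0.04 and -0.16 in VCaP and at -0.12 and -0.45 in LNCaP, while that of CFL1 stood at -0.59 and -0.73.

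In all, 1477 genes changed the same way, and 10 of them also differed between the lines. Every array carried the knockdown in Cy5, so a gene that labels better with Cy5 reads as higher in both lines whether or not it changed. Without any single VCaP array the count was 562 (VCaP-sh1 replicate 1), 592 (VCaP-sh1 replicate 2), 555 (VCaP-sh2 replicate 1) or 638 (VCaP-sh2 replicate 2), without the LNCaP-sh2 array 2250, and with each line fitted on its own arrays 69. Across genes, which are not independent replicates, the mean log2 ratios of the lines had Pearson's r = 0.447, with 0.285 to 0.391 for the 8 pairs of single arrays.

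**Figure D2:**
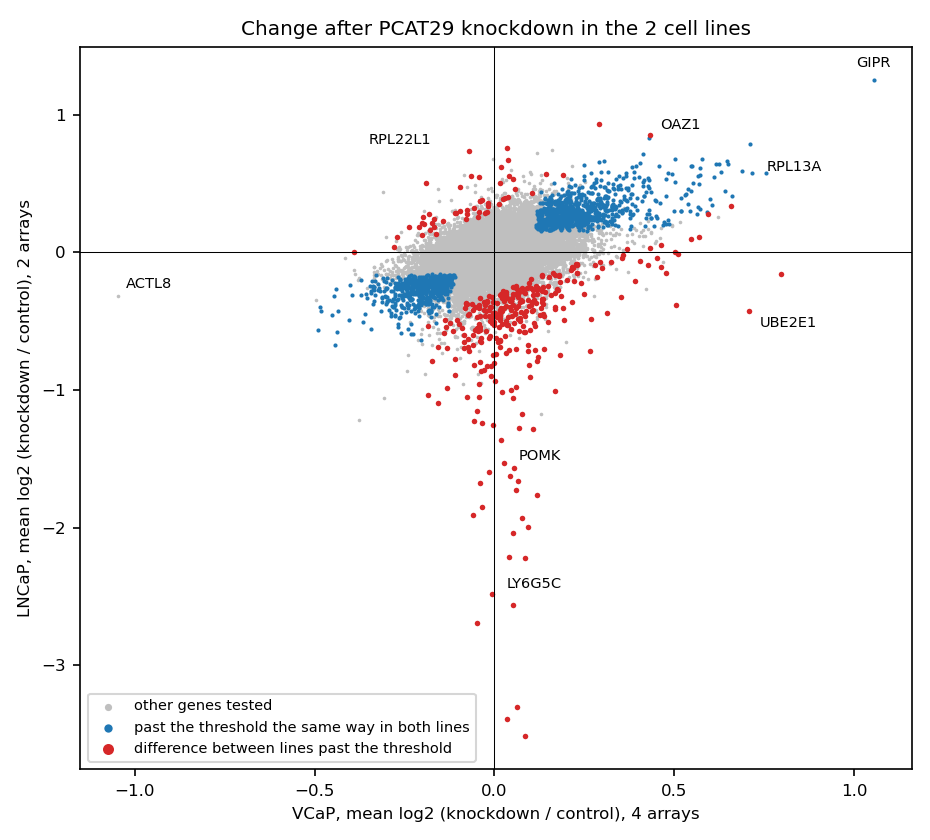
Mean log2 ratio of knockdown over control in VCaP (4 arrays, horizontal axis) against LNCaP (2 arrays, vertical axis), 1 point per gene tested. Red points differed between the lines, and blue points passed the same way in both without differing. GIPR is high in both lines, and LY6G5C and POMK lie far below 0 on the LNCaP axis and near 0 on the VCaP axis. Genes saturated or not well above background in a line are drawn at their measured ratio.

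The difference between the lines was tested directly, a comparison in which a dye bias common to all arrays cancels. UBE2E1 rose in VCaP and fell in LNCaP (0.71 ± 0.21 and -0.42 ± 0.06, log2, SD), with a difference of -1.13 ± 0.12 (SE, limma adjusted p = 0.00193). The zinc transporter SLC39A7 did the same (0.51 and -0.38, difference -0.89 ± 0.13, adjusted p = 0.0153). LY6G5C, TDRD10, POMK, GNG13 and ORAI3 were lower in LNCaP than in VCaP by differences of -2.47, -1.78, -1.56, -1.39 and -1.25 (log2), with the control of TDRD10 well above background on 3 of the 4 VCaP arrays. RPL22L1 was higher in LNCaP by 0.80 ± 0.10 and RPL13 by 0.49 ± 0.06, as were DSEL, a dermatan sulphate epimerase relative, by 0.46 ± 0.09, ANKRD40 by 0.45 ± 0.07 and OAZ1 by 0.42 ± 0.06 (log2, SE). Other probes moved less between the lines, from -0.10 to -0.04, -0.02 to 0.45, 0.01 to 0.10 and 0.04 to 0.21 for RPL13, from 0.27 to 0.45 and 0.37 to 0.44 for OAZ1 and from 0.04 to 0.27 for DSEL (log2 ratio in VCaP to that in LNCaP). The call of DSEL was lost without any single VCaP array, that of OAZ1 without any but VCaP-sh2 replicate 2, that of ANKRD40 without any but VCaP-sh1 replicate 1, and that of DSEL also without the LNCaP-sh1 array, with adjusted p between 0.0553 and 0.123.

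In total 361 genes differed between the lines (limma, adjusted p below 0.05), 53 higher and 308 lower in LNCaP. Of these, 88 were not well above background in a channel on every array of a line, so that the size of their difference was not measured. TMCC2, LGI4, RGMA, ST18, DRD5, OR2W3 and NBL1 were among them. Saturated genes were not part of that count. SPON2, saturated on all 4 VCaP arrays, has only a bound there as well. All VCaP arrays lay on slide 1 and both LNCaP arrays on slide 2, so slide and line cannot be told apart. Without single VCaP arrays the count was 127 (VCaP-sh1 replicate 1), 126 (VCaP-sh1 replicate 2), 115 (VCaP-sh2 replicate 1) or 122 (VCaP-sh2 replicate 2), without the LNCaP-sh1 array 949 and without the LNCaP-sh2 array 3709. The share of these genes that was higher in LNCaP was 14.7%, against 34.6% in the scanner's own log ratio and 60.8% with median centring.

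Among the lists, p53 targets were lower in LNCaP than in VCaP by a mean of -0.19 (log2, camera adjusted p = 0.00328, and adjusted p = 0.895 with an estimated correlation), with 0 of 26 genes past the threshold and 3 lower when adjusted over the list alone. The list averaged -0.34 on the LNCaP-sh1 array and -0.04 on the LNCaP-sh2 array. PHLDA3 differed by -0.40 and DDB2 by -0.52, neither of which passed. The heat shock response was higher in LNCaP by 0.12 (camera adjusted p = 0.00788, and adjusted p = 0.895 with an estimated correlation), with 0 of 16 genes past the threshold and 1 higher when adjusted over the list alone. It averaged 0.20 on the LNCaP-sh1 array and 0.06 on the LNCaP-sh2 array. On the VCaP arrays it averaged -0.01 and -0.02 with hairpin 1 and -0.01 and 0.07 with hairpin 2, so the LNCaP-sh2 array lay within the VCaP range. The chaperone HSPA1A differed by 0.28, which did not pass and which was -0.41 with median centring and -0.070 in the authors' table.

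The last comparison asked whether the hairpins against PCAT29 gave the same changes. In VCaP, 3 genes differed between hairpin 2 and hairpin 1. IFIT1, an interferon-induced antiviral protein, was higher with hairpin 2 by 1.36 ± 0.06, MX1, an interferon-induced GTPase, by 1.06 ± 0.05, and the lactate transporter SLC16A3 by 1.07 ± 0.06 (log2, SE, limma adjusted p = 0.00513, 0.00513 and 0.00526). IFIT1 averaged -0.99 with hairpin 1 and 0.37 with hairpin 2, and MX1 -0.39 and 0.67. VNN2 at 0.74, MKNK2 at 0.55, SMG1 at -0.41, NEUROG3 at -0.42, SLC39A7 at -0.40, UBE2E1 at -0.36 and FKBP10 at -0.33 followed and did not pass. The calls of IFIT1, MX1 and SLC16A3 were lost without VCaP-sh2 replicate 1 (adjusted p = 0.194 for each) and without VCaP-sh2 replicate 2 (0.224), although the differences were then 1.37, 1.03 and 1.12, and 1.35, 1.08 and 1.03 (log2), and limma then called 0 genes, with 2726 and 1982 at an unadjusted p below 0.05. Without VCaP-sh1 replicate 1 the count was 28 and without VCaP-sh1 replicate 2 it was 19, and in the scanner's own log ratio limma called 0, with 2440 at an unadjusted p below 0.05.

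Across genes, the mean log2 ratios of hairpin 1 and hairpin 2 in VCaP had r = 0.681 and a covariance of 0.0104. The labels give the VCaP control 1 name on all arrays and do not say whether it was the same RNA. Unchanged groups were simulated against a shared control assumed to deviate as much as a single VCaP array, a size these data do not measure. That setting fixes r in advance, at 0.667, so r cannot tell a shared control from a shared change. The simulated covariance was 0.00419, and it rests on the same assumption. If the RNA was the same, an unknown part of the excess over 0 may come from the shared control. The difference of the covariances was 0.00624. In LNCaP the hairpins had r = 0.455 and a covariance of 0.0211.

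**Figure D3:**
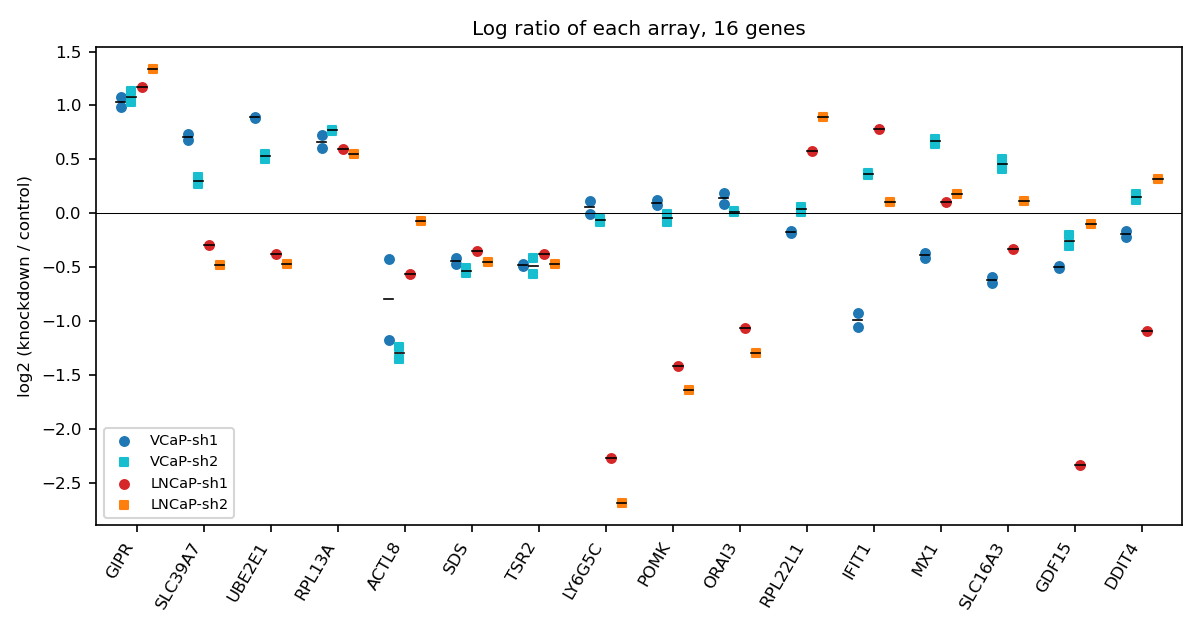
Log2 ratio of knockdown over control on each array for 16 genes, with circles for hairpin 1 and squares for hairpin 2, and a short line at the mean of each group. GIPR is above 0 on all 6 arrays, IFIT1 and MX1 part by hairpin in VCaP, and GDF15 and DDIT4 are far below 0 on the LNCaP-sh1 array.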

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

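The tests of saturated spots, of the covariance between arrays, of log ratios with no background correction and no loess, and of other cell types were chosen after the results were seen, while the tests of brightness, of other probes and of the correlation of the hairpin differences were written before. The genes in the next paragraph stand out because the change in LNCaP differed from that in VCaP by a limma test of the difference itself, which 361 genes passed, and the lists because they differed by camera; the patterns after it were picked from the results.

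Of the differences of at least 2-fold, 37 were lower in LNCaP. For 23 of them each channel was well above background on at least 1 array of each line, with saturation not considered. In LNCaP minus VCaP the log2 difference was -2.47 for LY6G5C, -1.78 for TDRD10, -1.56 for POMK, -1.39 for GNG13 and -1.25 for ORAI3. UBE2E1 differed by -1.13 and SLC39A7 by -0.89, each higher than control in VCaP and below 0 in LNCaP. RPL22L1 differed by 0.80, RPL13 by 0.49, DSEL by 0.46, ANKRD40 by 0.45 and OAZ1 by 0.42, all higher in LNCaP. Among the lists, p53 targets differed by a mean of -0.19 and the heat shock response by 0.12 (camera), both lost with an estimated correlation (adjusted p = 0.895) and with 0 of 26 and 0 of 16 genes past the threshold. Slide and line cannot be told apart for any of these.

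The first pattern is the 38 genes at least 2-fold lower in LNCaP, with a median of -1.58 (log2), -1.47 with hairpin 1 and -1.62 with hairpin 2; for 15 of them the VCaP control was not well above background, so that a fall could not have been seen, and the other 23 had medians of 0.03 in VCaP and -1.28 in LNCaP. Background correction and loess as the cause are argued against by the log ratios of the mean signals with neither step, only centred on each array's median, where the median of the 38 genes was -1.47. RNA from one of 5 listed other cell types (neuroendocrine, fibroblast, leukocyte, endothelial and erythroid, prostate basal) in the LNCaP control cannot be told apart from a change of these genes, since the lowest median of a type's markers was -0.081, but only 3 to 8 markers of a type were well above background in both LNCaP controls. Signal of single probes rather than of the gene cannot be told apart from a change of the gene, since only 3 other probes of 2 of these genes, with a median of -0.054, were above background in the control, and these did not fall. Only 34.2% of the 38 genes have a RefSeq symbol, against 62.6% of all genes tested. They were also dim, with a median log2 brightness of 7.20 against 8.93 for all genes tested. A knockdown effect limited to LNCaP stays open for the genes measured in VCaP.

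The second pattern is the shared rise of ribosomal protein genes and, more widely, of genes changed the same way in both lines. Dye bias tied to brightness is a candidate explanation. The 112 genes nearest in brightness outside the list had medians of 0.19 in VCaP and 0.21 in LNCaP, against ribosomal medians of 0.33 and 0.27. In 95% of random sets with 1 matched gene per ribosomal gene, a different matching, medians were 0.25 to 0.40 and 0.23 to 0.38. The 112 genes averaged 16.8 in log2 brightness, against 17.3 for the ribosomal genes. Ribosomal probes under other names may be among them, so brightness and ribosomal identity were not fully separated. The random sets drew repeatedly on those 112 genes. The brightest 2267 genes tested, dimmer on average than the ribosomal genes, had medians of 0.0039 in VCaP and -0.011 in LNCaP. Saturated spots are argued against, since only 1 of the 32 ribosomal genes had any, and the other 31 kept medians of 0.33 and 0.27. For all genes, the covariance of log ratios between arrays of different lines was 89.7% of that between arrays of the VCaP hairpins. The means were 0.00936 (SD 0.00065, 8 pairs) and 0.0104 (SD 0.00043, 4 pairs), further apart than either SD. The outcome set for a dye bias alone was therefore not met, nor was the one set against it. Correlations, which allow for the wider LNCaP log ratios, averaged 0.323 and 0.573. The VCaP value may also hold a part from a shared control RNA, which pairs of different lines would lack. A gene-specific dye bias and a shared response to the knockdown would both give a covariance between the lines, so these cannot be told apart without arrays that exchange the dyes. A response of both lines to the loss of PCAT29 stays open.

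The third pattern is the difference between the hairpins in LNCaP, where 58 genes differed at least 2-fold between 2 single arrays, whose own spread is unknown, 50 of them higher with hairpin 2. Background correction and loess are argued against, since 100% of the 58 genes differed at least 1.5-fold the same way in the log ratios with neither step. Across genes the hairpin difference in LNCaP had r = 0.051 with that in VCaP (0.016 to 0.061 over 4 array pairs), as a chance difference between the cultures or hybridizations of the single LNCaP arrays would give, and a hairpin effect limited to LNCaP would give the same. Glycolysis and hypoxia genes averaged higher with hairpin 2 by 0.15 in VCaP (camera adjusted p = 2.01e-11, and adjusted p = 0.486 with an estimated correlation) and by 0.37 between the single LNCaP arrays. Whether the cells, the RNA or the hairpin differed stays open with 1 array per hairpin.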

How the results depend on the processing

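Leaving out outlier and bright-background spots before the normexp fit was chosen after seeing the data, and the fit on all spots became an alternative then. Counts are given in the order VCaP, LNCaP, difference between lines, hairpin difference in VCaP and same way in both lines (3896, 4026, 361, 3 and 1477). Slide as a block was not run, since each slide holds 1 line; each line on its own arrays is the value within a slide.

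Without background correction 578 genes differed between lines and 8 between hairpins. The scanner's own log ratio gave 2412 in LNCaP, 217, 0 (limma, 2440 at an unadjusted p below 0.05) and 861, with 3 lists in VCaP and 2 in LNCaP; the authors' table gave 2282, 173, 0 (2251 unadjusted) and 822, with 3 lists and 1 list. Median centring gave 16249, 15490, 4041, 9 and 11738, with 9 and 12 lists. Scaling to equal spread gave 2647 in LNCaP. Probes above background in both channels gave 227 between lines and 7 between hairpins. The mean over probes gave 4 lists in VCaP and 11 in LNCaP. The fit on all spots gave 1228 in VCaP (73.9% higher), 1 between hairpins and 591 the same way, with 4 lists in VCaP. With 4 group means the counts were 8024, 8355, 3440 and 3702 the same way, with 2 lists in VCaP. With replicate arrays averaged they were 1, 1004, 39 and 1. Of the 63 calls of named genes 26 were kept, while the 3 between VCaP hairpins were not run there. On its own arrays each line gave 6987 and 173, 69 the same way and 3 lists in VCaP. Robust eBayes gave 78 between hairpins. A change of at least 1.5-fold as well left 22, 153, 109 and 7 the same way, by its construction. An estimated correlation gave 0 lists in either line, with adjusted p of at least 0.517 and 0.619, and fry gave 5 in VCaP.

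With the VCaP replicate number as a block, 2318 genes changed in VCaP and 8 differed between hairpins. Across genes, the difference between the replicate arrays of hairpin 1 had r = -0.057 with that of hairpin 2. This single comparison gave no sign that the numbers pair the arrays, and it cannot exclude a pairing. The block ended the calls of CARTPT in VCaP and no other named call there, brought VNN2 and MKNK2 past the threshold between hairpins, and was not run for the lists.

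The correlation between lines (0.447) was 0.358 in the scanner's log ratio, 0.733 with median centring, 0.519 with probes above background in both channels and 0.351 in the authors' table. That between VCaP hairpins (0.681) was 0.571, 0.925, 0.725 and 0.578 there, 0.717 without background correction and 0.621 without a filter.

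Leaving out 1 array gave 1179 to 6987 genes in VCaP, 2618 to 6255 in LNCaP, 115 to 3709 between lines, 0 to 28 between hairpins, 555 to 2250 the same way, 1 to 3 lists in VCaP, 1 to 13 in LNCaP and 55 to 63 calls of named genes. LNCaP gave 6255 genes and 13 lists without the LNCaP-sh2 array and 3172 and 1 without the LNCaP-sh1 array.

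RGMA in LNCaP turned to 0.094 without background correction and to 0.25 in the scanner's log ratio and the authors' table, where its other probe is the brighter. KLK3 in LNCaP turned to -0.19 with the mean over its probes. HSPA1A between lines turned to -0.41 with median centring and -0.070 in the authors' table. Median centring, which leaves the intensity trend in place and moves the median of all genes to 0.14 and 0.18, also turned NSFL1C to 0.013 and PSMD11 to 0.0050 in VCaP and, in LNCaP, TMPRSS2 to 0.11, ACSL3 to 0.024, CDK1 to 0.29, CENPF to 0.43, KIF23 to 0.20, KIF20A to 0.23, CDH1 to 0.26, GRHL2 to 0.028, and the means of the androgen-induced genes to 0.16, of G2/M and mitosis to 0.38, of the epithelial list to 0.25 and of the p53 targets to 0.14. Of the remaining values under alternatives, 2409 of single genes and 113 of lists kept their direction and their side of the threshold, 294 and 30 no longer passed, and 44 of single genes passed where they had not. Where no cause is named, the cause was not tested. Between 65.1% and 72.4% of spots stood well above background in a channel; without a filter on dim probes the counts were 3627 in VCaP and 3178 in LNCaP.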

Other observations

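The list tests between hairpins and the LNCaP genes named here were chosen after the data had been seen. With VCaP hairpin 2 against hairpin 1, interferon response genes were higher by a mean of 0.25 (log2, camera adjusted p = 1.28e-12, and adjusted p = 0.418 with an estimated correlation). The estimated correlation was -0.0062, below the preset 0.01, so correlation among these genes does not account for the loss. Of 28 genes, 2 rose, IFIT1 and MX1, and 14 rose when adjusted over the list alone. IRF9, a transcription factor of interferon signalling, was higher by 0.46 and ISG15, a ubiquitin-like modifier, by 0.30, which did not pass over all genes. In LNCaP the same list averaged 0.05 with hairpin 1 and 0.06 with hairpin 2, and IFIT1 went the other way, at 0.78 with hairpin 1 and 0.11 with hairpin 2. Glycolysis and hypoxia genes were higher with hairpin 2 in VCaP by 0.15 (camera adjusted p = 2.01e-11, and adjusted p = 0.486 with an estimated correlation), with 0 of 28 past the threshold and 13 higher when adjusted over the list alone, among them P4HA1, a collagen hydroxylase, at 0.42, the hexokinase HK2 at 0.41, DDIT4, an inhibitor of mTOR signalling, at 0.34 and VEGFA, a growth factor for blood vessels, at 0.31 (log2). Ribosomal proteins were higher by 0.06 (0.00419) and immediate early genes by 0.08 (0.0112), and G2/M and mitosis genes were lower, with a mean of -0.06 (0.0112), each by camera adjusted p and none with an estimated correlation (0.728, 0.486 and 0.486).

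In LNCaP, a set of genes was far lower with hairpin 1 than with hairpin 2. GDF15, a stress-induced cytokine, stood at -2.33 with hairpin 1 and -0.10 with hairpin 2 (log2), SHMT2, the mitochondrial serine hydroxymethyltransferase, at -1.58 and 0.05, CTH, an enzyme of cysteine synthesis, at -1.28 and -0.03, the stress factor DDIT3 at -1.17 and 0.33, the cystine transporter SLC7A11 at -1.10 and 0.44, DDIT4 at -1.09 and 0.32, and ATF4, the transcription factor of the amino acid response, at -0.64 and 0.38. The 26 genes of the amino acid response list averaged -0.42 with hairpin 1 and 0.12 with hairpin 2, and in VCaP that list differed between hairpins by 0.06, which did not pass (camera adjusted p = 0.0508). Glycolysis and hypoxia genes averaged -0.31 and 0.05 in LNCaP. RND3, a small GTPase that loosens actin fibres, stood at 1.31 with hairpin 1 and 0.05 with hairpin 2, and the copper carrier CP at 0.84 and -0.25.

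Histones averaged -0.18 with hairpin 1 and 0.12 with hairpin 2 in LNCaP, p53 targets -0.34 and -0.04, androgen-induced genes -0.22 and -0.02, fatty acid synthesis genes -0.21 and -0.02, luminal markers -0.20 and 0.0063, and oxidative stress response genes -0.23 and 0.02 (log2). With 1 array per hairpin, no test of a LNCaP hairpin difference is given.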
